A study of Homo sapiens with 6 samples.

How the data were processed

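Gene expression was measured in HuT102 cells, an established human T-cell line that carries the human T-cell leukaemia virus type 1 and is labelled as an adult T-cell leukaemia (ATL) line. Cells were treated for 16 h with the solvent DMSO or with 1 µM TAS-116 (pimitespib), an inhibitor of the chaperone HSP90. The labels put 3 samples in each of the 2 groups, and each sample was hybridised to its own array. The labels do not say that the samples of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical.

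Per the labels' protocols, total RNA was isolated on RNeasy columns with DNase treatment and labelled with Cy3 by the Low Input Quick Amp kit. The submitters' processing notes name Agilent Feature Extraction, and per the file headers its version was 10.7.3.1. The deposited scanner files give each spot's intensity on a linear scale, after spatial and multiplicative detrending by Feature Extraction, with its separate background correction off, per the file headers. The same files hold quality marks for outlying, saturated and dim spots. The authors also deposited a table of log2 values. Set against the scanner files, these values were log2 signals less the median of the 3 DMSO arrays. That median was exactly 0 for 100.0% of the 50737 probes. Their direction was TAS-116 over DMSO, with a correlation of 0.9997 or more across probes on each treated array. The scaling behind them is not given in the sources used here, and small differences from the scaling used here remained, with medians of at most 0.021 per array and 5th to 95th percentiles within -0.037 to 0.028. The medians of its columns over all probes were -0.040, 0.022 and 0 for DMSO replicates 1 to 3 and 0.041, 0.655 and 0.287 for TAS-116 replicates 1 to 3. This table served as an alternative.

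Each array held 62976 spots, of which 1319 were control spots. Control spots, spots marked as outliers (363 to 497 per array) and 84 probes for ERCC spike-in RNA were left out. The processed signal was taken to log2, the array's 75th percentile over non-control spots was subtracted, and spots of 1 probe were averaged, giving 50599 probes. All levels below are on this log2 scale, with 0 at the 75th percentile. Between 44.2% and 45.7% of non-control spots were well above background on an array, and 0 spots were saturated. Fewer spots were detected than not, so the percentile over detected probes was added as an alternative after seeing the data. The percentile over all non-control spots had been fixed beforehand and was kept.

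Probes were named through the reference gene table of assembly GRCh38.p14, by accession (28174 probes), symbol (2618) or older symbol (620), and 19187 kept the name in the files. Coordinates are those of the array's own annotation on hg19. A probe was tested if it was well above background on all 3 arrays of at least 1 group. For a gene with several such probes the brightest over all 6 arrays was taken, which left 16421 genes, 12950 of them with a symbol in the reference table.

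Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A second count took called genes with a change of at least 2-fold. Whether a gene list moved relative to all other tested genes was tested with camera at a preset correlation of 0.01, adjusted over the 23 lists. Camera with an estimated correlation and the rotation test fry were run beside it. Where a gene was well above background on no array of a group, its change is given as "at least N-fold". That bound sets the mean of the brighter group against the mean, per array, of the higher of the dim probe's own signal and the lowest signal among probes well above background.

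The lists, the tests, the alternative settings (unless marked as added) and the rule for named genes were fixed before the data were examined. The rule named the 6 genes with the largest rises and the 6 with the largest falls by fitted change (called, without overlap between the groups, detected in the brighter group, with a reference symbol). It also named the 4 HSP90 genes and, from each list, the 2 called members with the largest changes. Other genes are named where a count of 5 or fewer needs it or as further examples of a list, and were chosen after their values were seen. Some genes that the rule named are not reported here. The lists overlapped: LTA stood in 3 of them, and TNF, IL6, IL9, CXCL10, BIRC3 and BCL2L1, among others, stood in 2 each.

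All 6 arrays lay on 1 slide with 1 scan time, so slide and scan could not be tested as batches. The first row of the slide held the 3 DMSO arrays and TAS-116 replicate 1, and the second row held TAS-116 replicates 2 and 3. Slide row was therefore tested as a block and within the shared row. The second of these has 1 treated array, which is assumed to vary like the DMSO arrays, and both estimate the change from replicate 1. Other alternatives were normexp background correction (offset 50), quantile, median, spike-in and cyclic loess scaling, filters on dim probes, other rules for several probes, other variance models, the replicate number as a block, and leaving out each array.

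The fit was tested on simulated data with the means and spreads of these 16421 genes and 200 genes changed by known amounts. It recovered 10% of the genes changed 1.25-fold, 82% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, with 13 false calls among 157. With so few genes changed, the adjustment was stricter than in the real data, where 8353 genes were called. These shares therefore do not give the recovery of the real fit. With 1 list shifted by -0.3, camera at the preset correlation called it and 0 of the other lists, 1 of which had an unadjusted p under 0.05. The simulated genes were independent, so this leaves correlation between members untested. The number of arrays limits the precision.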

Results

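The series asked which transcripts change in an ATL cell line after 16 h with the HSP90 inhibitor TAS-116. It holds 6 single-colour arrays of HuT102 cells, 3 after DMSO and 3 after 1 µM TAS-116. Array signals were even across the samples. The 75th percentile of processed signal lay between 539.9 and 663.2, and 27245 to 28190 spots per array were well above background. TAS-116 replicate 2 stood apart, with a median processed signal of 37.1 against 18.4 to 22.9 on the other arrays. Across genes, arrays of the same group correlated at 0.995 to 0.997 and arrays of different groups at 0.978 to 0.981. The first principal component, with 79.2% of the variance, separated the groups.

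TAS-116 changed the transcripts of a large part of the tested genes. Of 16421 genes, limma called 8353 at an adjusted p under 0.05, of which 3356 rose and 4997 fell. At least 2-fold changes were called for 1053 genes, 605 up and 448 down, and at least 4-fold changes for 79 up and 76 down. The groups did not overlap for 9920 genes (60.4%), where chance gives 10% for 3 arrays against 3. The balance of rises and falls moved with the scaling. Rises made up 40.2% of the calls with the 75th percentile, 43.2% with spike-in scaling, 49.5% with quantile normalization, 50.9% after cyclic loess, 69.4% with the percentile over detected probes and 7.9% with median scaling. Median scaling moved the median log2 change of all genes from -0.05 to -0.53, and the percentile over detected probes moved it to 0.16. The 2-fold balance moved too, with 235 up and 2211 down under median scaling and 996 up and 251 down with the percentile over detected probes. With slide row as a block 5279 genes were called, and 4431 within the row that held both groups, where the treated arm is replicate 1 alone and the DMSO arrays supply the spread. The 2-fold count was 1034 and 1240 in those fits, and 560 with normexp background correction.

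Of the 6 genes with the largest falls, 4 encode secreted immune mediators. The chemokine genes CCL3L3 and CCL3 changed by -6.14 ± 0.06 (SE) and -5.26 ± 0.07 on the log2 scale, falls of 70.4-fold and 38.4-fold (limma adjusted p = 1.8e-07 and 3.7e-07). Their sequences are close, so the probes on chromosome 17 (hg19, 34523201 to 34523260 and 34415605 to 34415664) may share signal. SOCS3, which encodes an inhibitor of JAK-STAT signalling, dropped from 4.24 ± 0.01 to -0.85 ± 0.06 (SD, n = 3), a 34.1-fold fall with limma's adjusted p = 1.8e-07. Its probe lies on chromosome 17 from 76353127 to 76353186 (hg19). LTA, which encodes lymphotoxin alpha, fell 32.4-fold, and the immediate-early gene IER3 fell 15.3-fold. The cytokine gene IL17F fell 16.3-fold and was well above background on 1 of the 3 treated arrays.

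Ranked by fitted change, 5 of the 6 largest rises were in genes well above background on no DMSO array. Their fitted changes are set against background, so bounds are given for them and their order among rises is uncertain. RFPL2 rose at least 13.1-fold and RFPL1 at least 7.83-fold. These are related genes on chromosome 22 (hg19, 32586552 to 32586611 and 29838127 to 29838186), and their probes may share signal. CFAP251, named for cilia and flagella, rose at least 5.86-fold, PLAU, which encodes urokinase, at least 5.29-fold, and the pseudogene ABCA17P at least 2.71-fold. Genes detected in DMSO also passed the lowest of these bounds, among them HSPA1B at 5.22-fold and DDIT4 at 5.18-fold. CRACDL, detected on all 6 arrays, rose 10.6-fold from -1.80 ± 0.01 to 1.61 ± 0.07 (SD, n = 3).

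**Figure D1:**
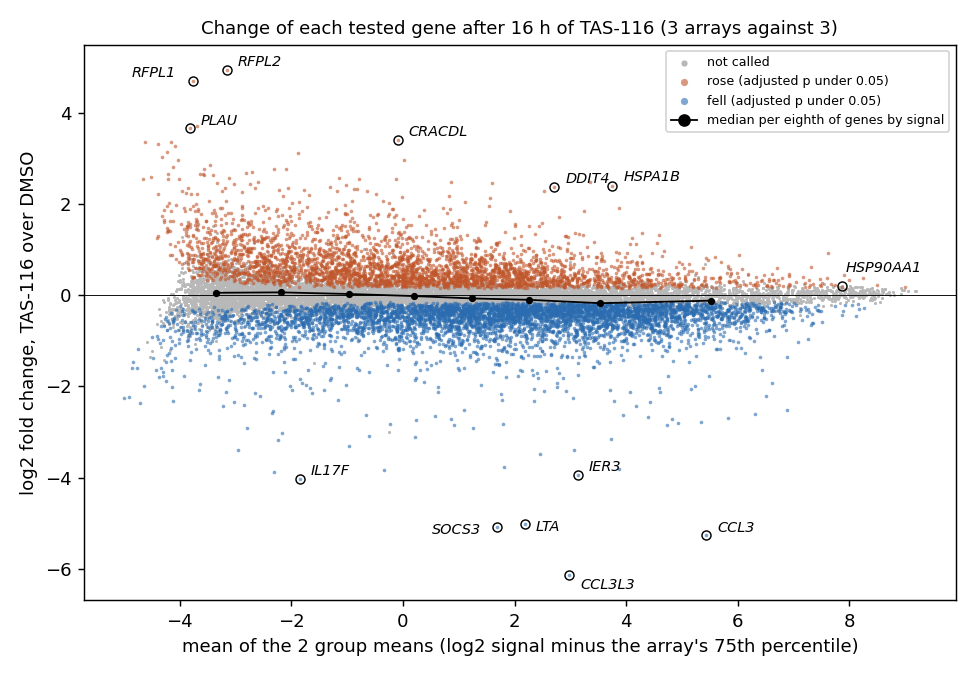
Each point is 1 of the 16421 tested genes, with the mean log2 signal relative to the array's 75th percentile on the horizontal axis and the log2 fold change of TAS-116 over DMSO on the vertical axis. Orange genes rose, blue genes fell and grey genes were not called, and the black line joins the medians of 8 groups of genes by signal.

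HSP90AB1, a cytosolic HSP90, rose by 0.42 ± 0.06 on the log2 scale (SE, limma adjusted p = 0.0011), but gave -0.06 under median scaling. That scaling lowered all genes together, moving their median log2 change from -0.05 to -0.53. For HSP90AA1, the other cytosolic form, the tested probe gave 0.19 ± 0.08 and did not pass (adjusted p = 0.074). Its 2 other detected probes rose by 0.76 and 0.68, and with median scaling the tested probe gave -0.28. HSP90B1, the form in the endoplasmic reticulum, gave 0.07 ± 0.05 and did not pass (adjusted p = 0.29), with -0.40 under median scaling. TRAP1, the mitochondrial form, fell by 0.43 ± 0.06, and by 0.41 within the shared slide row, with 1 treated array, where it was not called (adjusted p = 0.056).

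Of the 25 tested chaperones regulated by the heat shock factor HSF1, 17 rose and 1 fell, and 18 and 1 when adjusted over the list alone. The list's name calls them cytosolic, which HSPD1, HSPE1 and SERPINH1 are not. Under median scaling, which lowered all genes, 2 rose and the list median turned from 0.37 to -0.11, with the list still called up relative to other genes (adjusted p = 5.3e-06). HSPA1B, an inducible HSP70 gene, rose 5.22-fold from 2.56 ± 0.14 to 4.95 ± 0.11 (SD, n = 3). It is nearly identical to HSPA1A, which rose 2.22-fold. DNAJB4 rose 2.86-fold, BAG3 2.48-fold and DNAJB1 2.42-fold, while FKBP4, a co-chaperone of steroid receptors, fell 1.16-fold. The list was called up by camera (adjusted p = 9.5e-08), though not with an estimated correlation (adjusted p = 0.21).

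Other HSP90 family members and co-chaperones were not called as a list (camera adjusted p = 0.19), but were called down with no filter on dim probes (0.00057). The list's median was -0.10 in both. Without the filter the median log2 change of all tested genes was 0.28, against -0.05 with it. Every list is then set against a higher level, which bears on each such call below. Of 22 tested, 10 fell and 2 rose (SUGT1 and TSC1), with the same counts adjusted over the list alone, but 5 fell and 7 rose with the percentile over detected probes. FNIP2 fell 1.59-fold. The list's median relative to all genes turned from -0.05 to 0.07 with quantile normalization and to 0.04 with cyclic loess. Of 14 subunits of the TRiC chaperonin and of prefoldin, 5 fell and 1 (PFDN1) rose, also when adjusted over the list alone (2 and 4 with the percentile over detected probes), and the list was not called (adjusted p = 0.30; with no filter on dim probes, called down at 0.0068). PFDN2 fell 1.46-fold. PFDN6 fell by 0.59 on the log2 scale on the tested probe, but its second probe gave 0.61 and the mean of both gave 0.01. Of 32 proteasome subunits, 20 fell and 0 rose (21 and 0 adjusted over the list alone), led by PSMD12 at 1.54-fold and ADRM1 at 1.39-fold. These counts depend on the processing, with 7 falls with slide row as a block, 1 fall within the shared row (list median -0.30 in both, against -0.26), 7 falls and 3 rises after quantile normalization and 3 falls and 6 rises with the percentile over detected probes. ADRM1 fell by 0.48 on the log2 scale, and by 0.41 within the shared slide row, where it was not called (adjusted p = 0.092). The proteasome list was called down (adjusted p = 0.0017), a call absent with an estimated correlation (adjusted p = 0.50), quantile normalization (0.34), cyclic loess (0.11) and median scaling (0.13).

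Targets of the transcription factor NF-κB fell almost throughout. Of 26 tested, 24 fell and 0 rose, with the same counts when adjusted over the list alone, and 15 fell at least 2-fold. LTA and IER3 led the list, and the pathway inhibitors NFKBIA and TNFAIP3 fell 4.62-fold and 4.46-fold. The members that did not pass were EBI3 and CD82, at -0.04 and -0.08 on the log2 scale. Camera called the list down (adjusted p = 1.2e-12), but with an estimated correlation the adjusted p was 0.10. Of 18 STAT5 targets, 17 fell and 0 rose, also adjusted over the list alone. Beside SOCS3 these included OSM at 10.5-fold and CISH. PIM1, the remaining member, gave 0.06. The STAT5 list was called down (adjusted p = 1.6e-08; with an estimated correlation, adjusted p = 0.10).

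Among 20 tested cytokines and chemokines, 16 fell and 2 rose, also adjusted over the list alone, and 12 fell at least 2-fold. CCL4 fell 14.3-fold, TNF 14.1-fold, IL6 11.1-fold, IFNG 8.67-fold and CSF2 6.18-fold. CCL20 fell at least 8.99-fold and was well above background on no treated array. CCL17 rose 2.21-fold and LTB rose by 0.23 on the log2 scale. The list's adjusted p was 2.6e-07, and 0.14 with an estimated correlation. The list median of -2.86 became -2.15 with detection on all 6 arrays and -1.95 with normexp. With no filter on dim probes 33 members were tested, with a median of -0.25.

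The components of NF-κB and JAK-STAT signalling were not called as a list (adjusted p = 0.19), but were called down with no filter on dim probes (0.00057). Of 26 tested, 10 fell and 2 rose, among them BCL10, also adjusted over the list alone, but 7 fell and 10 rose with the percentile over detected probes. The list's median relative to all genes, -0.02, became 0.03 with quantile normalization and 0.02 with cyclic loess. STAT5A fell 2.71-fold from 4.19 ± 0.03 to 2.75 ± 0.06 (SD, n = 3). The kinase genes JAK1, JAK2 and JAK3 did not pass, with log2 changes of -0.05, -0.03 and 0.11.

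**Figure D2:**
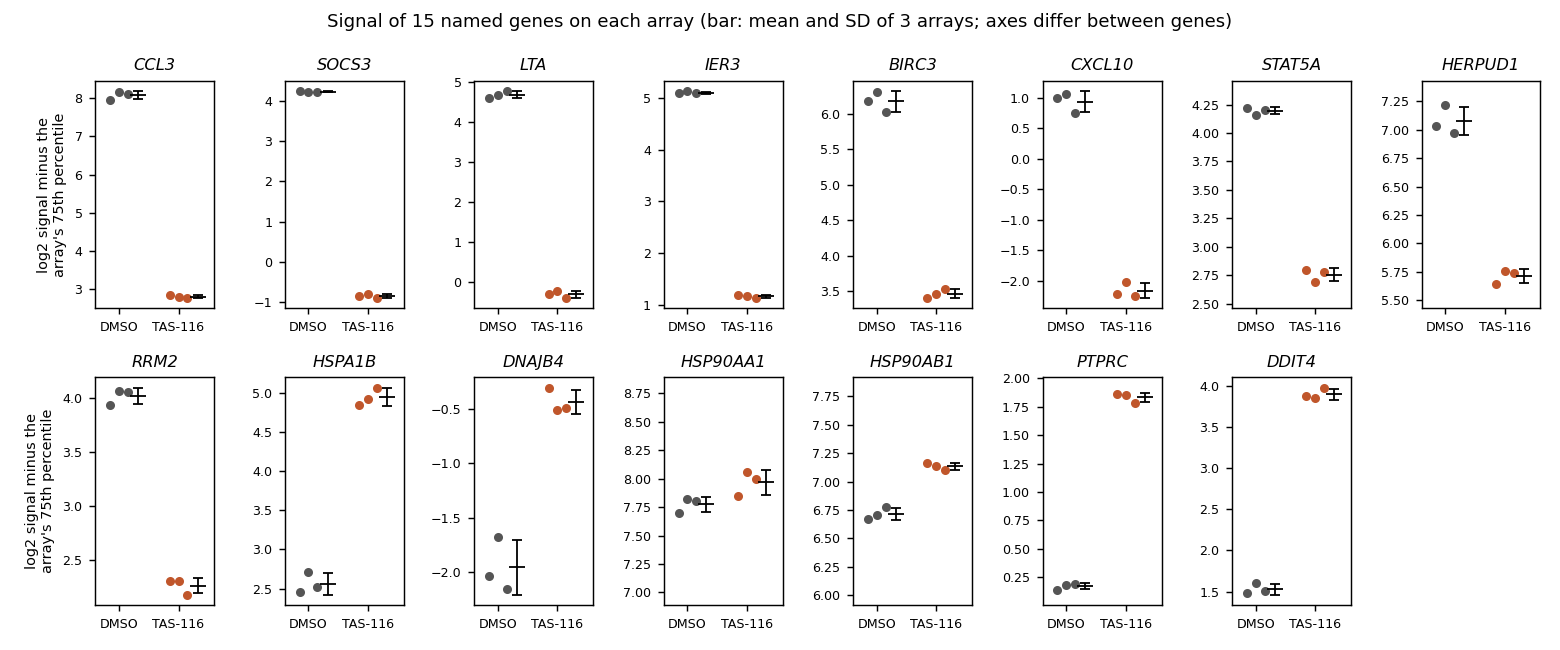
Log2 signal relative to the array's 75th percentile is plotted for 15 named genes on each of the 3 DMSO (grey) and 3 TAS-116 (orange) arrays, with the mean and SD of each group as a black bar. The treated arrays lie below all DMSO arrays for CCL3, SOCS3, LTA, IER3, BIRC3, CXCL10, STAT5A, HERPUD1 and RRM2, and above them for the others, with the smallest step for HSP90AA1.

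Surface and transcription factor genes of ATL cells fell more often than they rose. Of 19 tested, 12 fell and 4 rose, among them CD52, CADM1 and IKZF1, and 13 and 4 when adjusted over the list alone. TNFRSF8, which encodes CD30, fell 3.42-fold and TBX21, which encodes the transcription factor T-bet, 2.99-fold. The list was called down (adjusted p = 0.011; with an estimated correlation, adjusted p = 0.34). Genes of the T-cell receptor complex and its proximal signalling went the other way. Of 17 tested, 10 rose and 1 (VAV1) fell, also adjusted over the list alone. Under median scaling, which lowered all genes, 1 rose and 1 fell, and the list median turned from 0.38 to -0.10. The list was still called up relative to other genes there (camera adjusted p = 0.0037). PTPRC, which encodes the phosphatase CD45, rose 3.16-fold and the adaptor gene SLA 2.19-fold. A further PTPRC probe did not pass, at 0.35 on the log2 scale, while 2 others rose. This list was called up (adjusted p = 0.0013; with an estimated correlation, adjusted p = 0.21).

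Interferon-stimulated genes divided. Of 25 tested, 11 rose and 4 fell, and 12 and 4 when adjusted over the list alone. OASL rose 3.67-fold, IFIT1 3.39-fold and IFI44 2.90-fold. Among the falls, CXCL10 fell 8.54-fold. Camera called the list up (adjusted p = 0.022), without a call with an estimated correlation (adjusted p = 0.27), under median scaling (0.14) or with no filter on dim probes (0.31).

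Genes of DNA replication and targets of E2F fell together. Of 37 tested, 35 fell and 1 (MCM6) rose, also adjusted over the list alone, and TYMS gave 0.05. CDC6, which loads the replicative helicase, fell 2.55-fold and was well above background on 2 of the 3 treated arrays. With slide row as a block its log2 change went from -1.35 to -1.42, with an adjusted p of 0.051. RRM2, a subunit of ribonucleotide reductase, fell 3.37-fold on the tested probe. Its other 2 probes gave 0.47 and 0.42, the second of these a called rise, and the mean over probes did not pass (-0.29, adjusted p = 0.074). The list was called down (adjusted p = 8.0e-09; with an estimated correlation, adjusted p = 0.27). Of 37 mitosis genes, 7 rose and 9 fell, also adjusted over the list alone, with NEK2 up by 0.77 and CDC25C up by 0.58 on the log2 scale. There were 22 rises and 4 falls after quantile normalization, 17 and 4 after cyclic loess and 21 and 3 with the percentile over detected probes. The mitosis list was not called (adjusted p = 0.39), but was called up after quantile normalization (0.0033) and cyclic loess (0.033). Of 19 replication-dependent histone genes, whose sequences are close, 10 fell and 1 rose, also adjusted over the list alone (list adjusted p = 0.16; with no filter on dim probes, called down at 0.00055). With quantile normalization 4 fell and 4 rose, and with the percentile over detected probes 2 fell and 7 rose. H1-3 fell 1.52-fold. H2BC12 rose 1.58-fold on the tested probe, and its other probe did not pass.

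Targets of p53 mostly rose, with 14 of 23 up and 1 down, also adjusted over the list alone. Under median scaling, which lowered all genes, 2 rose and 2 fell. The list was still called up relative to other genes there (camera adjusted p = 0.00039). TP53INP1 rose 8.65-fold, from a level well above background on 2 of the 3 DMSO arrays, and the kinase gene PLK3 fell 2.59-fold. CCNG1 and SESN1 rose by 1.35 and 1.06 on the log2 scale, and CDKN1A, which encodes the inhibitor p21, did not pass at 0.30. The list was called up (adjusted p = 0.00016; with an estimated correlation, adjusted p = 0.10). Apoptosis regulators divided, with 6 up and 14 down of 29, also adjusted over the list alone, and no call for the list (adjusted p = 0.27; with no filter on dim probes, called down at 0.0068). With the percentile over detected probes 9 rose and 9 fell. BIRC3 and BCL2L1, which encode inhibitors of apoptosis, fell 6.52-fold and 3.75-fold.

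MYC and genes of ribosome biogenesis fell in 27 of 31 tested, with 0 rises (27 and 1 adjusted over the list alone). MYBBP1A fell 2.34-fold and BOP1 2.24-fold, and MYC itself fell by 0.53 on the log2 scale. The members that did not pass were NPM1, NPM3, NOB1 and HSPD1. The list was called down (adjusted p = 1.3e-08; with an estimated correlation, adjusted p = 0.25). Cholesterol synthesis genes fell in 17 of 21, with 1 rise (TM7SF2), also adjusted over the list alone. There were 11 falls under median scaling, 11 with the percentile over detected probes and 8 within the shared slide row. INSIG1, which holds sterol-regulated processing in check, fell 3.05-fold. This list's adjusted p was 0.00016, and 0.34 with an estimated correlation. In the hypoxia and glycolysis list 15 of 26 fell and 5 rose, also adjusted over the list alone. HK2 and PFKP, of early glycolysis, fell 2.55-fold and 1.73-fold. The rises were in KDM3A, BNIP3L, PFKFB4, PFKL and ALDOC. With the percentile over detected probes 8 members of this list fell and 7 rose. The list's adjusted p of 0.049 became 0.50 with an estimated correlation and 0.17 with quantile normalization. The call was lost under 13 of the 20 alternative settings in which this list was tested.

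Genes of the unfolded protein response of the endoplasmic reticulum fell in 14 of 23, with 0 rises (15 and 0 adjusted over the list alone). HERPUD1 fell 2.57-fold from 7.08 ± 0.13 to 5.71 ± 0.06 (SD, n = 3) and XBP1, a transcription factor of this response, 2.30-fold. The list was called down (adjusted p = 0.00016; with an estimated correlation, adjusted p = 0.27). In the ATF4 and integrated stress response list 13 of 24 fell and 4 rose, also adjusted over the list alone, without a call (adjusted p = 0.12; with no filter on dim probes, called down at 0.00029). DDIT4 rose 5.18-fold and CEBPB fell 4.17-fold, and the other rises were in SESN2, GPT2 and PHGDH. With the percentile over detected probes 8 members of the ATF4 list fell and 7 rose, and under median scaling 8 fell and 1 rose. NRF2 targets and metallothioneins gave 6 rises and 6 falls among 25, also adjusted over the list alone, and no call (adjusted p = 0.39). There were 10 rises and 4 falls after quantile normalization and 13 and 3 with the percentile over detected probes. MT1F rose 2.62-fold, with probes of metallothionein genes open to shared signal, and ABCC1 fell 1.58-fold. Among markers of other cell types 11 of 30 were detected well enough to be tested. VWF, NKG7, CSF1R and CD79A rose and CD68 fell, also adjusted over the list alone, without a call for the list (adjusted p = 0.16). VWF rose 3.17-fold to a level of -2.21, with a second probe at 0.01 on the log2 scale, and NKG7 2.03-fold.

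**Figure D3:**
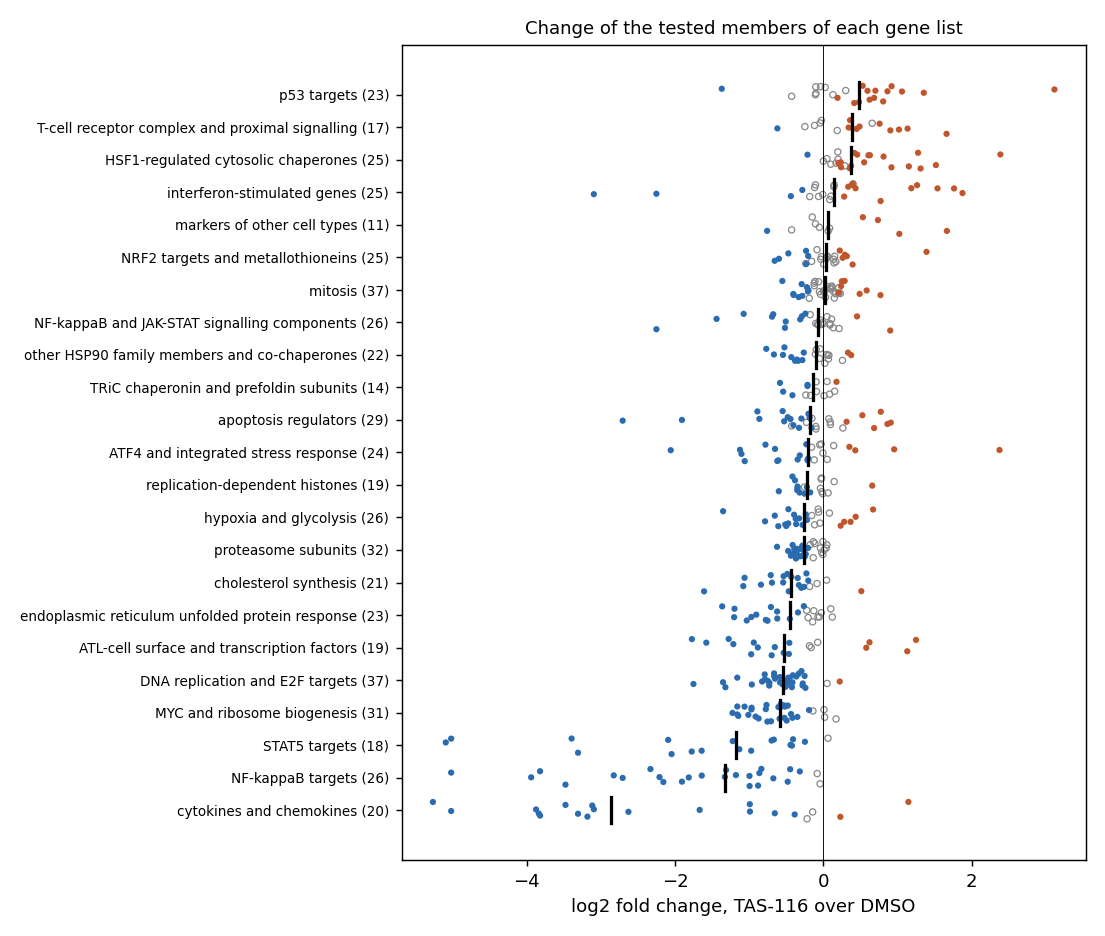
Each row is 1 of the 23 gene lists with its number of tested members in brackets, each point is the log2 fold change of 1 member, and the black bar is the median. Filled points passed an adjusted p of 0.05 (orange up, blue down), and the medians run from -2.86 for cytokines and chemokines to 0.48 for p53 targets.

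Of the 23 lists, 14 were called at the preset correlation and 0 with an estimated one. With the estimated one, the lowest adjusted p was 0.10, and the unadjusted p was under 0.05 for NF-κB, STAT5, cytokines and p53. The 2 versions of camera differ in more than the correlation. For p53 targets the estimated correlation was -0.007, below the preset 0.01, yet camera's unadjusted p rose from 6.0e-05 to 0.011. The lost calls therefore do not show that correlation between members undid them. Relative to the median of all genes, the 14 called lists kept their direction with normexp, quantile normalization and cyclic loess. With no filter on dim probes the interferon list turned from 0.20 to -0.14, and the other 13 kept theirs. The interferon list's own median was 0.145 with the filter and 0.142 without it, while that of all genes went from -0.05 to 0.28. Scalings that shift each array by 1 constant cannot change a list's median relative to all genes.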

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

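The percentile over detected probes and cyclic loess were chosen after seeing the data, and the other alternatives were planned. The counts of called genes and of 2-fold changes stayed within 1.5 times of the reported ones under quantile, spike-in and cyclic loess scaling, the authors' values, detection on all 6 arrays, other rules for probes, trend and robust variance, and the replicate block. Median scaling called 3952 genes (314 up) and 2446 at least 2-fold (235 up, 2211 down). The array median lay among spots below background, where replicate 2 of TAS-116 was higher. Under it HSP90AA1 gave -0.28, HSP90AB1 -0.060 and HSP90B1 -0.40, and rises and falls were even for p53 targets (2 and 2), the T-cell receptor list (1 and 1) and interferon-stimulated genes (3 and 3), while 2 HSF1-regulated chaperones rose (list median -0.11). The percentile over detected probes gave 6283 rises and 2775 falls, and 996 and 251 at least 2-fold. Each of these scalings changes 1 constant per array and so moves all genes together. Normexp, whose offset draws dim signals together, gave 560 genes at least 2-fold, 275 up and 285 down. Without a filter on dim probes 5309 genes passed, 2973 of them down, among 36384 tested. There camera turned the mitosis and NRF2 lists (medians 0.027 and 0.051) to down, against a median of 0.28 for all genes. It called 19 lists, 6 of them down that were not called with the filter (other HSP90 genes, TRiC and prefoldin, ATF4, NF-κB and JAK-STAT components, histones, apoptosis), while the interferon list lost its call. A 1.5-fold criterion gave 3252 genes, 1520 up and 1732 down.

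With slide row as a block 5279 genes passed (2081 up, 3198 down), and 4431 within the row that held both groups (1909 up, 2522 down). Both fits compare fewer arrays or spend a degree of freedom, and the second has 1 treated array. The mean of all probes turned PFDN6 to 0.013, since its 2 probes disagree. Cyclic loess turned the TRiC and prefoldin list from -0.14 to 0.011. It also raised the median log2 change in the brightest eighth of genes from -0.12 to 0.03, and in the next brightest from -0.18 to -0.04. Whether the list followed signal level alone was not tested. Camera with an estimated correlation called 0 lists. Fry, which does not compare a list with other genes, called 21. Slide and scan as a block were not run, as there was 1 of each. The hypoxia and glycolysis list lost its call under 13 alternatives. The count of members called in a list's main direction moved by over 1.5 times under at least 1 alternative for all 9 uncalled lists and for 7 of the 14 called ones. These were HSF1-regulated chaperones (2 to 23 rises), the proteasome (1 to 22 falls), the T-cell receptor list (1 to 11 rises), p53 (2 to 16 rises), cholesterol (8 to 18 falls), hypoxia (7 to 16 falls) and interferon (3 to 16 rises).

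Leaving out each array gave 7017 to 7723 called genes, 1027 to 1156 at least 2-fold and 13 to 14 lists. Without TAS-116 replicate 2, which stood apart, these were 7630, 1115 and 13. Of 1053 genes changed at least 2-fold, 1019 to 1048 were called in the same direction in each of these fits. The replicate numbers did not pair the samples (correlations of deviations -0.03, -0.10 and -0.07), and the replicate block gave 7398 called genes, 1052 at least 2-fold and 13 lists. Only 44.2% to 45.7% of spots were well above background, so changes in dim genes are bounds or carry the largest errors.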

Other observations

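The tests of scaling and of a tilt on the balance of rises and falls were chosen only after the result was seen, as were the test of slide row on interferon-stimulated genes and the look at probes as bright as that of HSP90AA1. Beyond the lists of the report, several families stood out by their values. The genes of this paragraph and the next were singled out after their values were seen. Of 8 tested SNAR genes, which encode small non-coding RNAs on chromosomes 19 and 2, 7 fell at least 2-fold, by up to 2.86 on the log2 scale for SNAR-G2. SNAR-A3 fell 5.73-fold from a level of 8.14 ± 0.09 (SD, n = 3), among the brightest on the array. The remaining member, SNAR-C4, gave 0.71 ± 0.50 (SE) and did not pass. The family's sequences are close, so its probes may share signal and may amount to few independent measurements. The vault RNA genes VTRNA2-1, VTRNA1-2 and VTRNA1-3 fell 3.91-fold, 2.78-fold and 2.72-fold. How well the column isolation and the labelling kit recover small RNAs such as these was not tested, so the source of their signal is uncertain. A candidate explanation, lower output of RNA polymerase III, was tested on 5 other transcripts of that polymerase. Of these 3 rose (RNU6ATAC, RMRP and RN7SK) and 0 fell. Their median of 0.44 lay at the 99.57th percentile of 10000 signal-matched random lists, so these signals showed no shared fall. They passed through the same isolation and labelling, so their source is uncertain too, and the test does not decide. Only 5 of the 15 listed transcripts could be tested, and their levels were measured rather than the polymerase's output. Lower output for the SNAR and vault RNA genes is therefore not excluded. Camera gave p = 0.032 for a rise, and p = 0.094 with an estimated correlation.

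MIR155HG, the host gene of a microRNA, fell 13.7-fold, and the cytokine gene IL27 7.54-fold. Immediate-early genes were among the larger falls, with FOS down 7.08-fold, NR4A3 6.28-fold, DUSP2 4.35-fold, EGR2 4.21-fold and IER2 3.81-fold. The feedback genes SPRED1 and SPRED2 fell 4.64-fold and 3.56-fold, with SPRED1 well above background on 2 of the 3 treated arrays. Whether this extends to a list of immediate-early and MAPK feedback genes not yet looked at was then tested. Of 20 tested members 13 fell and 0 rose, 8 of them at least 2-fold, led by SPRY2 (3.02-fold). SPRY1, SPRY4 and NR4A2 did not pass, at 0.33, 0.13 and 0.09 on the log2 scale. Nor did IER5, DUSP6, PHLDA1 and FOSB, at -0.15, -0.19, -0.39 and -1.43. The median of all 20, -0.86, lay at percentile 0 of 10000 signal-matched random lists. Camera gave p = 8.3e-05, and p = 0.013 with an estimated correlation. Lower activity of MAPK signalling is a hypothesis consistent with this, and no protein or phosphorylation was measured.

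With 10 ways to split 6 arrays into 3 and 3, a share under 0.05 cannot be reached. The real split called 8353 genes, 1053 of them at least 2-fold, and the highest of the other splits called 0 of either, while 125 to 316 genes had an unadjusted limma p under 0.05 there. In each case 1 split, the real one, gave as many. Each other split holds treated and DMSO arrays in both arms, so the treatment itself widens the spread within arms. The 0 calls there follow from this and decide nothing. For gene lists the real split called 14 and the highest other split 12, and each other split keeps part of the treatment's shift, as it sets 2 arrays of a group and 1 of the other against the reverse. Slide row as the source of the 2-fold changes was tested through TAS-116 replicate 1, which shared the row of the DMSO arrays. Its changes over the 1053 genes, against 1 DMSO array, followed those of replicates 2 and 3, against the others. The slope was 0.952 (median over the 3 choices of that array, 95% bootstrap interval 0.940 to 0.968). These changes were thus also present within the row of the DMSO arrays. The genes had been called with replicate 1 included, which leaves out most changes of row 2 alone. A low slope was therefore unlikely, and the test does not decide how far slide row moved other genes.

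More genes fell than rose, with rises at 40.2% of the calls. Array scaling, a signal-dependent tilt and a true excess of falls cannot be told apart here, and no measure of total RNA per cell was used. Rises reached 69.4% with the percentile over detected probes and 43.2% with spike-in scaling. Both add 1 constant per array, so the share moves with the constant and does not show which is right. Quantile normalization gave 49.5%. Cyclic loess gave 50.9%, but it centres the change at each signal level, so a share near 50% follows from the method. The median log2 change was -0.12 in the brightest eighth of genes (-0.14, -0.11 and -0.12 for TAS-116 replicates 1 to 3). In the dimmest eighth it was 0.05, from 0.22 in replicate 2 against 0.005 and 0.0003 in replicates 1 and 3. Of the 1053 genes changed at least 2-fold, 1046 kept their call and direction after cyclic loess.

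HSP90AA1 gave 0.19 on its brightest probe and 0.76 and 0.68 on the others. Compression of bright probes was tested over genes with 2 or more probes. The brighter probe's change over the dimmer's had a median ratio of 0.788 where the brighter probe was in the top eighth of signal and 0.773 elsewhere, a difference of 0.016 (95% bootstrap interval -0.063 to 0.078). That argues against compression over the top eighth as a whole. The prediction was too wide for this probe, which lies at the 99.2nd percentile, where 1 other gene pair was available. Of 191 other probes at least as bright in DMSO, 83 of them for ribosomal protein genes, 5 were called up, by at most 0.38 (SOD1), and 12 down, among them CCL3 and SNAR-A3 with log2 changes of -5.26 and -2.52. HSPB1 speaks against compression at this level. Its 2 bright probes rose by 0.92 ± 0.07 and 0.96 ± 0.08 (SE) to 8.07 and 8.09, above the 7.97 of the HSP90AA1 probe after TAS-116, and its dim probe rose by 0.96 ± 0.12. No spot was saturated. This is 1 gene, however, so compression at the very top and a difference between transcripts cannot be told apart for HSP90AA1.

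Interferon-stimulated genes rose in 11 of 25 cases while 4 fell. After cyclic loess 100% of the 11 kept their rise, but it raised the median change at most signal levels, so losses were unlikely. The size of the tilt argues against it for these 11. The median log2 change was at most 0.06 in any eighth of genes by signal, and the lowest of the 11 rises was 0.28. At least 90.9% of the 11 kept their rise without any 1 treated array. The 11 had been called with all treated arrays included, so few could be lost. That test therefore does not decide on a single treated array. Slide row was tested through TAS-116 replicate 1, which shared the row of the DMSO arrays. The mean change of the 11 in it was 0.950 of that in replicates 2 and 3, with separate DMSO arrays (95% bootstrap interval 0.885 to 1.05). The rises of the 11 were thus also present within that row. They had been called with replicate 1 included, so a low ratio was unlikely. The ratio therefore does not decide how far slide row moved the list. Only 8 members of the list were called up with slide row as a block and 7 within the shared row, but the median change of the 11 was 0.77 without and 0.79 with either correction. The calls ended because the median SE grew from 0.07 to 0.11 and 0.13. A response to the treatment is a hypothesis, and a part played by slide row or by a single array is not excluded.

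Among targets of FOXO transcription factors in the lists of the report, TP53INP1, DDIT4, SESN1 and GADD45A rose by 3.11, 2.37, 1.06 and 0.92, while BCL6 and BCL2L11 fell by 0.70 and 0.53. A list of 17 other tested FOXO targets was compared with signal-matched random lists. Its median of 0.26 lay at the 99.68th percentile, with 10 up (CCNG2 6.84-fold, FBXO32 4.35-fold) and 4 down (S1PR1, SOD2, KLF6 and IL7R). Camera gave p = 0.019, but p = 0.11 with an estimated correlation. Higher FOXO activity may be involved, as a hypothesis from these data.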
